A study of Mus musculus with 28 samples.

How the data were processed

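The series holds 28 mouse samples, of which 24 are libraries of rearranged Tcra transcripts and 4 are chromosome conformation (4C) samples. The 4C samples had no file among those used and were not analysed here. Per the labels' protocols, total RNA was taken from sorted CD4+CD8+ double-positive (DP) thymocytes, or from naive T cells of the spleen, of mice 4 weeks old. A template-switch RACE primer and an antisense primer in the constant gene Trac amplified the transcripts, a primer pair that is the same for all V and J segments. The labels mention no molecular identifiers, so a read is a PCR product and not a separate transcript. All intervals and detection limits given here therefore cover counting error only.

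Per the file headers, the authors deposited for each library a table of clones, with the V and J segments that each clone matched, its CDR3 and its read number. The clone count column holds whole read counts, per the file headers, and was not normalised by the authors. The deposited clone fraction is the clone count divided by the total of its library. It summed to between 0.999 and 1.001 in each library and was used only for that check. The aligner, the assembler, their versions and their filters are not given in the sources used here.

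Read counts were summed per V segment and per J segment in each library, over all rearrangements, productive or not. The segment listed first was used where a clone matched several. Between 46.4% and 71.5% of the reads of a library listed more than 1 V segment, because much of the Trav array is duplicated, and between 0.00141% and 0.0456% listed more than 1 J segment. Values of single Trav segments with a near-identical copy are therefore uncertain, and counts that leave these reads out or sum each Trav family are given as alternatives. Of the 92 V names in the files, 91 could be placed along the locus by the RefSeq annotation of assembly GRCm38.p6, which was used for order only. The allele of strain 129 may differ from that order. The 87 ranked Trav segments were split into 3 groups of 29 by distance from the Traj array (J-proximal, central and J-distal). The 47 J names were split into Traj61 to Traj42, Traj41 to Traj22 and Traj21 to Traj1, where Traj61 lies next to the V array and Traj1 next to Trac.

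Samples were grouped by the labels: wild type (WT, strain 129), HYa and INT1-2-KO DP thymocytes, HYa naive spleen T cells, and DP thymocytes of Tcrd-CreER × Rosa26-fl-STOP-fl-ZsGreen mice sorted as ZsGreen+ or ZsGreen− after 1 mg tamoxifen. Nothing beyond the replicate label says that the libraries of a group came from separate mice, so p-values measure the spread between these samples, which may be partly technical. Replicates were compared by a chi-square test of their V-J counts, and every pair of a group differed by more than the counting noise of reads. No library thus looked like another of its group deposited again, and pairs from different groups were not compared. That test does not show separate mice, and libraries were counted as samples by their labels.

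The comparisons, tests, segment lists and rule for naming segments were chosen before the data were examined, except where a later choice is stated. Segment counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the library size set to all rearranged reads, no composition factor and the filterByExpr filter. The 12 steady-state libraries were fitted together, as were the 12 ZsGreen libraries. The time course was a slope over the 8 ZsGreen+ libraries, given as log2 change per 24 h. A segment was called at a Benjamini-Hochberg adjusted p under 0.05 over the segments of its kind. DESeq2 1.42.0 and TMM factors served as alternatives. Shares were tested by exact two-sided permutation tests. Single values were computed per library. They were the mean Traj number, the share of J-proximal Trav, the rank correlation over reads between V and J position (positive where J-proximal Trav join the Traj next to the V array), and the effective number of V-J pairs (the exponential of the Shannon entropy, after thinning the compared libraries to the same depth with 10 draws). Benjamini-Hochberg values were computed over these values within each comparison and over the blocks that combine a V group with a J group. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.

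The text names, for each comparison, up to 6 Trav and 6 Traj per direction, while Trdv are described as a list. These are the segments of largest log2 change that passed the threshold, reached a mean share of 0.5% in either group and had no overlap between the libraries of both groups. At 12 and 24 h, and for 72 h against 48 h, examples of them are given. For the time course the share had to be reached at any time, and the slope had to keep its sign without any single library. A further 12 lists were described in each comparison: the 3 V groups, the 3 J groups, the Trav also named as Trdv, Traj61 to Traj56, Traj9 to Traj2, Trav17 to Trav23, Trav1 with Trav2, and Trdv joined to Traj. Pairs known from invariant NKT and MAIT cells were also counted. The prior rule for leaving out a clonotype of a modified allele asked for over 20% of reads in every HYa library and under 1% in every WT library. It was not met, because the Trav17-Traj57 clonotype passed 20% in 2 of 6 HYa libraries, and the clonotype was kept. Results without it (clones within 3 substitutions of its CDR3) were added after its share was seen, as were time-course results without libraries under 30000 reads and the comparison of 72 h with 48 h.

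A share of a whole moves when other segments move. The test was checked on simulated counts for the 92 V names, in 10 sets with 20 segments changed. Every segment was given the same dispersion of 0.05 around the mean shares of the reference group. The rates below hold for that spread only, and J segments were not simulated. For HYa against WT it recovered 35.5% of segments changed 1.5-fold, 88.5% of those changed 2-fold and all of those changed 4-fold. For INT1-2-KO against WT it recovered 16.5% at 1.5-fold and 84.5% at 2-fold, and for ZsGreen+ against ZsGreen− at 48 h 4.5% and 63.0%. With no segment changed at most 0.116% were called. With segments changed 4-fold, the shares of unchanged segments shifted by a median log2 of −0.39 in the HYa simulation, and 22.0% of unchanged segments were called, against 1.86% with TMM factors. The same figures were 18.0% for INT1-2-KO and 12.6% for ZsGreen at 48 h. Calls on shares are therefore statements on shares, and splits under another scaling are given where they differ. Other alternatives were unique rearrangements in place of reads, productive rearrangements only, no filter on low segments, a fit on the compared groups alone, log2 hours, the replicate number as a block, and leaving out each library in turn.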

Results

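Rearranged Tcra transcripts were sequenced from sorted CD4+CD8+ double-positive (DP) thymocytes, the stage at which Trav segments are joined to Traj segments. The steady-state groups were wild type (WT, strain 129, n = 3), HYa (n = 4) and INT1-2-KO (n = 3), with naive T cells of the HYa spleen (n = 2) beside them. HYa is known as an allele that carries an already rearranged alpha chain gene of a receptor for the male antigen H-Y. INT1 and INT2 are known as CTCF-binding elements in the Tcrd part of the locus. In a time course, mice with Tcrd-CreER and a ZsGreen reporter received 1 mg tamoxifen, which marks cells that express the recombinase from the Tcrd locus. ZsGreen+ DP cells were read at 12, 24, 48 and 72 h (n = 2 each) and ZsGreen− DP cells at 12 h (n = 1), 24 h (n = 1) and 48 h (n = 2).

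The 24 libraries held 20796 to 1436573 rearranged reads, with a median of 447395. The shallowest were the ZsGreen− libraries at 12 h (20796 reads) and 24 h (21600 reads), replicate 2 of ZsGreen+ at 24 h (24097 reads) and replicate 2 of ZsGreen+ at 72 h (25854 reads). In these 4 libraries the productive share was 61.4%, 58.5%, 52.3% and 58.4%, in that order. INT1-2-KO replicate 3 had 49.3% productive reads, against 71.7% and 71.6% in the other INT1-2-KO libraries and 68.4% ± 1.21 in WT. Values below are shares of the reads of a library, as mean ± SD. The standard error (SE) beside a log2 change is approximate. It is the absolute log2 change over the square root of the F statistic of edgeR. Single Trav values are uncertain where the array holds near-identical copies.

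The first comparison asked how an allele that starts from a rearranged gene changes which segments are joined. A single Trav17-Traj57 clonotype made up 16.6% (exact binomial 95% interval 16.5 to 16.8), 8.28% (8.21 to 8.35), 21.3% (21.3 to 21.4) and 22.4% (22.3 to 22.5) of the reads of HYa thymus replicates 1 to 4. In the WT libraries it was at most 0.00117%. Trav17 rose from 0.283% ± 0.121 in WT (n = 3) to 17.4% ± 6.53 in HYa (n = 4), a log2 change of 5.94 (SE 0.56, adjusted p = 8.93e-07), and Traj57 rose from 2.26% ± 0.0550 to 17.2% ± 6.45 (log2 2.92, SE 0.34, adjusted p = 6.61e-06). With the clonotype left out, Trav17 had a log2 change of −0.12 (adjusted p = 0.885) and Traj57 one of −5.92 (adjusted p = 6.30e-06). Several segments that lie between Trav17 and Traj57 in the reference order had almost no reads in HYa, while Trav19 kept 10668 and Trav18 376. Trav21-dv12 had 0 of 3001366 HYa reads, against 34950 WT reads, and was at least 16751-fold lower against a floor of 3 counts over the group. Trav23 also had 0 reads, against 1183 in WT (at least 567-fold lower), and Traj58 had 1 read, against 47897 in WT (68869-fold lower, counting interval 12360 to 2.7202e+06).

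At the other end of the V array, the J-distal Trav1 fell from 4.15% ± 1.21 in WT to 0.714% ± 0.348 in HYa (log2 −2.54, SE 0.32, adjusted p = 1.94e-05). Trav2 fell from 1.40% ± 0.233 to 0.357% ± 0.0799 (log2 −1.97, adjusted p = 6.52e-06). Lower values were also called for Trav3-1 (log2 −1.89), Trav6-1 (log2 −1.45) and Trav5-1 (log2 −1.36). The J-proximal Trav13-4-dv7 rose from 0.637% ± 0.145 to 1.10% ± 0.252 (log2 0.79, adjusted p = 0.0238), and Trav16 from 1.18% ± 0.0815 to 1.68% ± 0.236 (log2 0.51, adjusted p = 0.0244). Among J segments, Traj35 fell from 1.13% ± 0.00931 to 0.764% ± 0.00756 (log2 −0.57, SE 0.08, adjusted p = 5.66e-05). Traj47, Traj28, Traj37 and Traj26 had log2 changes of −0.52, −0.47, −0.46 and −0.46, all called on shares. With TMM factors these 4 were not called, with log2 changes of −0.27, −0.22, −0.21 and −0.22 (adjusted p = 0.140, 0.212, 0.140 and 0.224).

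Of the 29 J-proximal Trav tested, 4 rose, 4 fell and 21 did not pass in HYa, and 4 rose and 4 fell when adjusted over the list alone. The number higher was 9 with TMM factors, 12 with DESeq2, 10 with unique rearrangements and 12 without the clonotype, with 4 lower in each. None of the 29 central Trav passed, also when adjusted over the list alone, while edgeR with TMM factors called 1 of them higher, and DESeq2, unique rearrangements and the setting without the clonotype called 2 each. Of the 28 J-distal Trav, 14 fell and 14 did not pass (15 fell when adjusted over the list alone, 9 with unique rearrangements). Of the single-copy families Trav17 to Trav23, Trav17 rose, Trav19, Trav20, Trav21-dv12 and Trav23 fell, and Trav18 did not pass, with the same numbers when adjusted over the list alone (1 higher, 4 lower). With unique rearrangements or without the clonotype, 0 of them were higher and 4 lower. Trav1 and Trav2 both fell, also when adjusted over the list alone. All 3 Trdv joined to Traj fell, also when adjusted over the list alone (2 with TMM factors, with unique rearrangements or without the clonotype), from 61570 of 2087388 WT reads to 11 of 3001366 HYa reads. Of these, Trdv5 was near the floor, with 25 WT reads against 0 HYa reads. Of the 10 Trav also named as Trdv, 2 rose and 1 fell (3 and 1 when adjusted over the list alone). Among J segments, Traj61 to Traj42 had 2 higher and 6 lower of 14 (2 and 6 when adjusted over the list alone), and Traj41 to Traj22 had 14 lower of 18 (14 when adjusted over the list alone). For Traj41 to Traj22 the number lower was 1 with TMM factors, 1 with DESeq2, 0 with unique rearrangements and 1 without the clonotype. Traj61 to Traj42 had 3 higher and 2 lower with TMM factors, 4 and 2 with DESeq2, 1 and 2 with unique rearrangements, and 2 and 3 without the clonotype. Traj21 to Traj1 had 1 lower of 14, and 0 when adjusted over the list alone, with TMM factors, with DESeq2, with unique rearrangements or without the clonotype. Of the 4 tested in Traj61 to Traj56, 1 rose and 2 fell, also when adjusted over the list alone, against 2 and 2 with TMM factors or DESeq2, 0 and 2 with unique rearrangements, and 1 and 3 without the clonotype. None of the 6 in Traj9 to Traj2 passed in edgeR, DESeq2 or when adjusted over the list alone.

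The J-proximal Trav took 47.1% ± 9.29 of HYa reads, against 27.1% ± 3.12 in WT (exact two-sided permutation p = 0.0571, adjusted p = 0.0762). The rank correlation of V and J position was 0.830 ± 0.0654 in HYa and 0.494 ± 0.00752 in WT (exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.0571). The effective number of V-J pairs at 194717 reads was 584 ± 231 in HYa and 1922 ± 108 in WT (exact permutation p = 0.0286, adjusted p = 0.0571). Without the clonotype, the difference in J-proximal share went from 20.02 to 9.40 percentage points (exact permutation p = 0.0857), that in rank correlation from 0.336 to 0.222 and that in effective pairs from −1338 to −717 (exact permutation p = 0.0286 for both). With unique rearrangements they were 7.40 (exact permutation p = 0.0857), 0.203 and −706 (exact permutation p = 0.0286 for both), and with reads naming 1 gene the J-proximal difference was 38.2 and that in effective pairs −759. The setting with reads naming 1 gene did not leave out the clonotype. It drops the reads listing several V segments, 57.9% to 64.5% of a HYa thymus library, so its shares are of a smaller whole. J-distal Trav joined to Traj61 to Traj42 made up 0.738% ± 0.0670 of HYa reads and 3.90% ± 0.367 of WT reads (exact permutation p = 0.0286, adjusted p = 0.0643). The mean Traj number was 32.7 ± 3.78 in HYa and 28.7 ± 0.932 in WT (exact permutation p = 0.171, adjusted p = 0.171), and the difference turned to −0.977 without the clonotype and −1.74 with unique rearrangements. In all, edgeR called 25 of 90 V segments (4 higher, 21 lower) and 23 of 46 J segments (2 higher, 21 lower). The V split was 10 higher and 18 lower with TMM factors and 14 and 21 with DESeq2, with the median of all V segments moved by 0.14 and 0.18 on the log2 scale. The J split was 3 and 3 with TMM factors and 4 and 3 with DESeq2, with the median moved by 0.25 and 0.27, and 15 J segments were called without WT replicate 2 and 38 without HYa replicate 2.

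**Figure D1:**
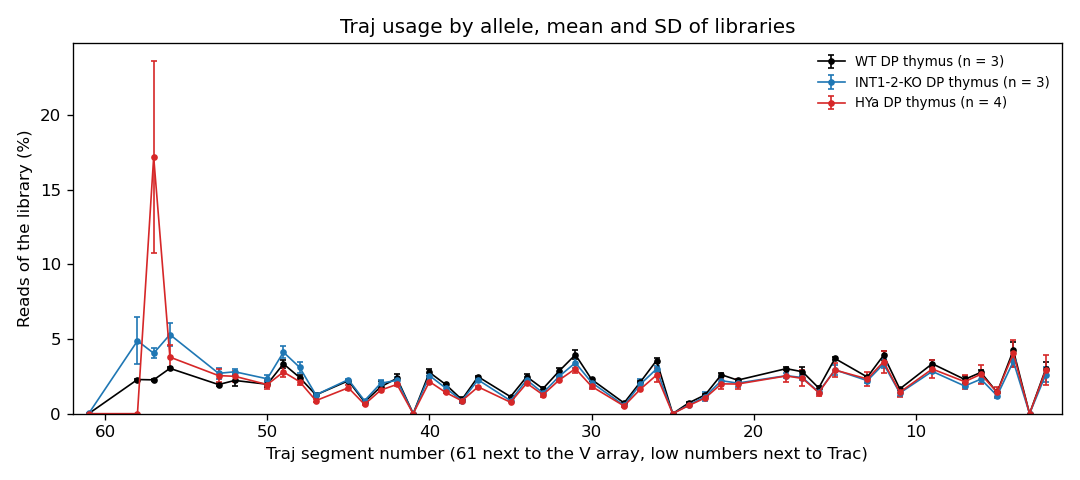
Use of each Traj segment in DP thymocytes of WT (n = 3), INT1-2-KO (n = 3) and HYa (n = 4) mice. The x axis is the Traj number, from the segment next to the V array to that next to Trac, and the y axis is the share of the reads of a library in percent. Points are means and bars SD. Traj57 stands at 17.2% in HYa and 2.26% in WT, while Traj58 is at 2.29% in WT, 4.88% in INT1-2-KO and close to 0 in HYa.

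The INT1-2-KO comparison asked which segments are joined without these CTCF-binding elements. The elements lie outside the transcripts read, so their loss could not be seen in these files. In INT1-2-KO DP cells, 10 of 29 J-proximal Trav and 2 of 4 of Traj61 to Traj56 were called higher and 4 of 28 J-distal Trav lower than in WT (n = 3 each), while unique rearrangements called 11, 3 and 10. Trav21-dv12 rose from 1.66% ± 0.226 to 3.90% ± 0.290 (log2 1.23, SE 0.21, adjusted p = 0.00281), and Trav19 from 0.973% ± 0.243 to 2.24% ± 0.0874 (log2 1.20, SE 0.23, adjusted p = 0.00281). Traj58 rose from 2.29% ± 0.0669 to 4.88% ± 1.57 (log2 1.09, SE 0.17, adjusted p = 0.000355). INT1-2-KO replicate 3, the library with 49.3% productive reads, had 6.73% of its reads in Traj61 to Traj58, against 4.10% and 3.86% in replicates 1 and 2, and a J-proximal share of 43.97%, against 35.99% and 39.5%. Trav1, in contrast, fell from 4.15% ± 1.21 to 1.19% ± 0.184 (log2 −1.80, SE 0.35, adjusted p = 0.00281).

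Further J-proximal segments called higher were Trav20 (log2 1.47, adjusted p = 0.0352), Trav14-3 (log2 0.93), Trav6-7-dv9 (log2 0.91) and Trav3-4 (log2 0.89). Further J-distal segments called lower were Trav2 (log2 −1.58, adjusted p = 0.00138), Trav3-1 (log2 −1.30) and Trav5-1 (log2 −0.97). Traj56 rose from 3.04% ± 0.0587 to 5.30% ± 0.759 (log2 0.80, adjusted p = 0.0054), and Traj53 had a log2 change of 0.47 (adjusted p = 0.0408). Traj35 fell by 0.38 on the log2 scale (adjusted p = 0.0080) and Traj28 by 0.36 (adjusted p = 0.0239). Neither was called with TMM factors, where log2 was −0.28 (adjusted p = 0.0626) for Traj35 and −0.25 (adjusted p = 0.132) for Traj28, and Traj53 was not called with unique rearrangements (log2 0.36, adjusted p = 0.0593).

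Of 29 J-proximal Trav, 10 rose and 19 did not pass in INT1-2-KO (12 rose when adjusted over the list alone). Of 29 central Trav none passed in edgeR, DESeq2 or when adjusted over the list alone, and 1 was lower without the clonotype. Of 28 J-distal Trav 4 fell, also when adjusted over the list alone, against 5 with TMM factors, 7 with DESeq2, 10 with unique rearrangements and 8 without the clonotype. The clonotype was at most 0.00142% of an INT1-2-KO library, and the J-distal median log2 was −0.679 with and without it. The counts without the clonotype thus reflect the fit shared with the HYa libraries, not a change in INT1-2-KO or WT shares. Trav17 to Trav23 had 3 higher of 6, and 6 when adjusted over the list alone. Trav1 and Trav2 both fell, also when adjusted over the list alone. Of the Trav also named as Trdv, 4 of 10 rose, also when adjusted over the list alone. Of 3 Trdv joined to Traj, Trdv1 rose from 1.5001% ± 0.228 to 3.83% ± 0.478 (log2 1.35, SE 0.27, adjusted p = 0.00299), with 1 called when adjusted over the list alone. Traj61 to Traj42 had 3 higher of 14 (4 when adjusted over the list alone, 8 with DESeq2), and Traj61 to Traj56 had 2 higher of 4 (3 when adjusted over the list alone). Of 18 in Traj41 to Traj22, 2 fell, also when adjusted over the list alone, with 1 for unique rearrangements and 0 with TMM factors or DESeq2. None of 14 in Traj21 to Traj1 and none of 6 in Traj9 to Traj2 passed in edgeR, DESeq2 or when adjusted over the list alone.

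The J-proximal Trav made up 39.8% ± 4.01 of INT1-2-KO reads, and the V-J rank correlation was 0.705 ± 0.00857, against 27.1% ± 3.12 and 0.494 ± 0.00752 in WT. The mean Traj number was 32.3 ± 1.20, against 28.7 ± 0.932, and the effective number of V-J pairs at 534821 reads was 1479 ± 45.6, against 1934 ± 110. Each of these 4 exact two-sided permutation tests gave p = 0.1 (adjusted p = 0.1), the smallest that 3 against 3 libraries can give, with no overlap between groups. In edgeR, 15 of 90 V segments (11 higher, 4 lower) and 5 of 46 J segments (3 higher, 2 lower) were called, and the J split was 4 and 0 with TMM factors and 8 and 0 with DESeq2, which moved the J median by 0.11 and 0.16. Without WT replicate 1 or WT replicate 2 each, 9 V segments were called, and without WT replicate 1, WT replicate 2 or INT1-2-KO replicate 2, 3 J segments were called, against 8 without WT replicate 3. Without INT1-2-KO replicate 3, 15 V segments (7 higher, 8 lower) and 5 J segments (2 higher, 3 lower) were called, with differences of 10.7 percentage points in J-proximal share and 3.11 in mean Traj number. With reads naming 1 gene the difference in mean Traj number was 7.47.

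The spleen comparison asked which rearrangements of HYa DP thymocytes are found in naive T cells (2 spleen against 4 thymus libraries). Trav16d-dv11 rose from 2.50% ± 0.468 in thymus to 5.79% ± 0.0452 in spleen (log2 1.21, SE 0.20, adjusted p = 0.000841), and Trav16 from 1.68% ± 0.236 to 3.6035% ± 0.0164 (log2 1.10, SE 0.17, adjusted p = 0.000626). Traj30 rose from 1.83% ± 0.159 to 3.87% ± 0.245 (SE 0.13, adjusted p = 3.50e-06), and Traj35 from 0.764% ± 0.00756 to 1.57% ± 0.00312 (log2 1.04, SE 0.09, adjusted p = 2.52e-07). Traj2, at the Trac end of the array, fell from 2.91% ± 1.02 to 0.910% ± 0.0927 (log2 −1.68, SE 0.25, adjusted p = 4.72e-05). The Trav17-Traj57 clonotype was 6.11% (exact binomial 95% interval 6.06 to 6.15) and 8.32% (8.28 to 8.37) of reads in the spleen libraries.

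Other V segments higher in spleen were Trav12-2 (log2 1.18), Trav12-3 (log2 1.08), Trav3-1 (log2 0.90) and Trav8d-2 (log2 0.86). Lower V segments were Trav4-2 (log2 −1.85), Trav4d-2 (log2 −1.77), Trav1 (log2 −1.46), Trav13d-4 (log2 −1.28), Trav13-4-dv7 (log2 −1.10) and Trav6-5 (log2 −0.92). Traj33, Traj47, Traj22 and Traj26 had log2 changes of 0.96, 0.95, 0.95 and 0.87, and Traj56, Traj23, Traj4 and Traj6 changes of −0.90, −0.87, −0.87 and −0.56. The J-proximal Trav had 4 higher and 5 lower of 29 (6 and 5 when adjusted over the list alone), the central Trav 3 and 6 of 29 (3 and 6 when adjusted over the list alone) and the J-distal Trav 1 and 4 of 28 (1 and 4 when adjusted over the list alone). With TMM factors these were 7 and 5, 5 and 6, and 2 and 4, with DESeq2 7 and 5, 6 and 6, and 2 and 7, and without the clonotype 4 and 6, 2 and 7, and 1 and 10. Traj61 to Traj42 had 5 higher and 2 lower of 14, also when adjusted over the list alone, 3 higher and 5 lower with TMM factors or DESeq2, 3 and 2 with unique rearrangements, and 3 and 3 without the clonotype. Traj41 to Traj22 had 10 higher and 1 lower of 18, also when adjusted over the list alone, and 8 and 2 with TMM factors, with DESeq2 or without the clonotype. Traj21 to Traj1 had 1 higher and 3 lower of 14, 0 and 3 when adjusted over the list alone, 0 and 4 with unique rearrangements, and 0 and 6 with TMM factors, with DESeq2 or without the clonotype. Of Traj61 to Traj56, 2 of 4 fell, and of Traj9 to Traj2, 3 of 6 fell, both with the same counts when adjusted over the list alone (1 of the former with unique rearrangements). Among the thymus libraries, replicate 2 stood apart with a high share of Traj9 to Traj2, as described below, which adds to the difference from spleen. Trav17 to Trav23 had 1 lower of 6, Trav1 and Trav2 had 1 lower of 2, and the Trav also named as Trdv had 1 higher and 2 lower of 10 (1, 1, and 1 and 3 when adjusted over the list alone). No Trdv of 3 passed in edgeR, DESeq2 or when adjusted over the list alone.

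The mean Traj number was 31.2 ± 0.902 in spleen and 32.7 ± 3.78 in thymus, and the J-proximal share 43.6% ± 2.42 and 47.1% ± 9.29. The rank correlation was 0.774 ± 0.0173 and 0.830 ± 0.0654, and the effective number of pairs 821 ± 60.7 and 584 ± 231. The exact two-sided permutation p was 0.6, 0.733, 0.4 and 0.333 (all adjusted p = 0.733, smallest possible 0.0667), and without the clonotype each of these differences changed sign. In edgeR, 23 of 90 V segments (8 higher, 15 lower) and 22 of 46 J segments (16 higher, 6 lower) were called. The V split was 15 and 15 with TMM factors and 16 and 18 with DESeq2, the J split 11 and 13 with both, and the J median moved by −0.22 and −0.21. Without spleen replicate 1 or spleen replicate 2, 5 and 3 V segments were called.

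The time course asked how the joined segments change after cells expressed the recombinase from Tcrd. At 12 h the ZsGreen+ cells used the J-proximal Trav and the first Traj, and later times moved to the J-distal Trav and the last Traj. ZsGreen− cells also had lower values at later times, with a mean Traj number of 28.8, 23.98 and 18.7 and a J-proximal share of 25.7%, 21.6% and 11.3% at 12, 24 and 48 h (n = 1, 1 and 2). Per segment, the log2 difference between ZsGreen+ and ZsGreen− cells changed from 12 to 48 h by 3.15 for Traj15 and by −0.73 for Traj58. Among J segments this change was negative only for Traj58, Traj57 (−0.29) and Traj56 (−0.10), and positive for all others. Only effect sizes are given here, because there was 1 ZsGreen− library at 12 h. These are changes of shares with no other scaling run, so a common shift of shares was not separated. Trav21-dv12 fell from 14.7% at 12 h to 5.95%, 1.67% and 1.90% at 24, 48 and 72 h, a log2 slope of −1.18 per 24 h (SE 0.20, adjusted p = 0.00342, n = 8). Trav1 rose from 0.0326% to 0.348%, 1.38% and 3.90% (log2 2.34 per 24 h, SE 0.38, adjusted p = 0.00342). Traj57 stood at 10.4%, 5.16%, 0.779% and 1.70% (log2 −1.09 per 24 h, SE 0.27, adjusted p = 0.00363), and Traj12 rose from 0.182% to 0.700%, 2.78% and 6.26% (log2 1.95 per 24 h, SE 0.21, adjusted p = 1.96e-05).

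Other V segments with rising slopes were Trav2 (log2 2.32 per 24 h), Trav6-1 (1.97), Trav5-1 (1.95), Trav3-1 (1.95) and Trav4d-4 (1.52). Falling V segments were Trav20 (log2 −0.98 per 24 h), Trav19 (−0.98), Trav13-4-dv7 (−0.90), Trav3-4 (−0.83, adjusted p = 0.04996) and Trav16 (−0.73). Traj11, Traj9, Traj2, Traj13 and Traj16 rose with slopes of 1.99, 1.88, 1.84, 1.83 and 1.74. Traj58, Traj56, Traj49, Traj52 and Traj53 fell with slopes of −1.03, −1.02, −0.92, −0.91 and −0.90. Of 28 J-proximal Trav, 15 fell (14 when adjusted over the list alone). The number lower was 20 with TMM factors, 22 with DESeq2 and 17 with unique rearrangements. Of 28 central Trav, 14 rose, also when adjusted over the list alone, while 13 rose and 2 fell with TMM factors, 14 and 2 with DESeq2, and 17 and 1 with unique rearrangements. Of 28 J-distal Trav, 16 rose, also when adjusted over the list alone. In Traj61 to Traj42, 11 of 13 fell (12 when adjusted over the list alone or with unique rearrangements, 13 with TMM factors or DESeq2). In Traj21 to Traj1 all 14 rose, also when adjusted over the list alone. Traj41 to Traj22 had 8 of 16 higher (7 when adjusted over the list alone), 7 higher and 2 lower with TMM factors, 7 and 7 with DESeq2, and 8 and 1 with unique rearrangements. All 3 of Traj61 to Traj56 fell and all 6 of Traj9 to Traj2 rose, also when adjusted over each list alone. Trav17 to Trav23 had 4 lower of 6 (5 when adjusted over the list alone), Trav1 and Trav2 both rose, and both Trdv joined to Traj fell, the latter lists also when adjusted over the list alone. Trav also named as Trdv had 1 higher and 4 lower of 10, also when adjusted over the list alone.

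The J-proximal Trav share fell from 61.02% ± 0.116 at 12 h to 54.6% ± 0.158, 30.8% ± 2.36 and 23.7% ± 0.967 (Pearson r = −0.974, exact permutation p = 0.000397, adjusted p = 0.00159, Spearman rho = −0.976, exact permutation p = 0.000794, n = 8). The mean Traj number fell from 48.2 to 43.0, 30.8 and 26.4 (r = −0.979, exact permutation p = 0.000794, adjusted p = 0.00159, rho = −0.976, exact permutation p = 0.000794, n = 8). Without the 72 h libraries, the farthest from the median time, r was −0.989 and −0.999 (exact permutation p = 0.0111 for both, n = 6). The effective number of V-J pairs at 24097 reads rose with time (r = 0.892, exact permutation p = 0.00397, adjusted p = 0.00529, rho = 0.878, exact permutation p = 0.0103, and r = 0.978 without the 72 h libraries). The V-J rank correlation was 0.179, 0.283, 0.256 and 0.387 at the 4 times (r = 0.868, exact permutation p = 0.00635, adjusted p = 0.00635, rho = 0.781, exact permutation p = 0.0349), and it rests on the 72 h libraries, since r was 0.565 without them (exact permutation p = 0.211, n = 6). These were 4 relations, tested two-sided. In edgeR, 47 of 87 V segments (30 higher, 17 lower) and 33 of 43 J segments (22 higher, 11 lower) had a slope past the threshold. The V split was 27 and 24 with TMM factors and 29 and 26 with DESeq2, with medians moved by −0.19 and −0.21, and the J split was 21 and 20 with DESeq2, with the median moved by −0.61.

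**Figure D2:**
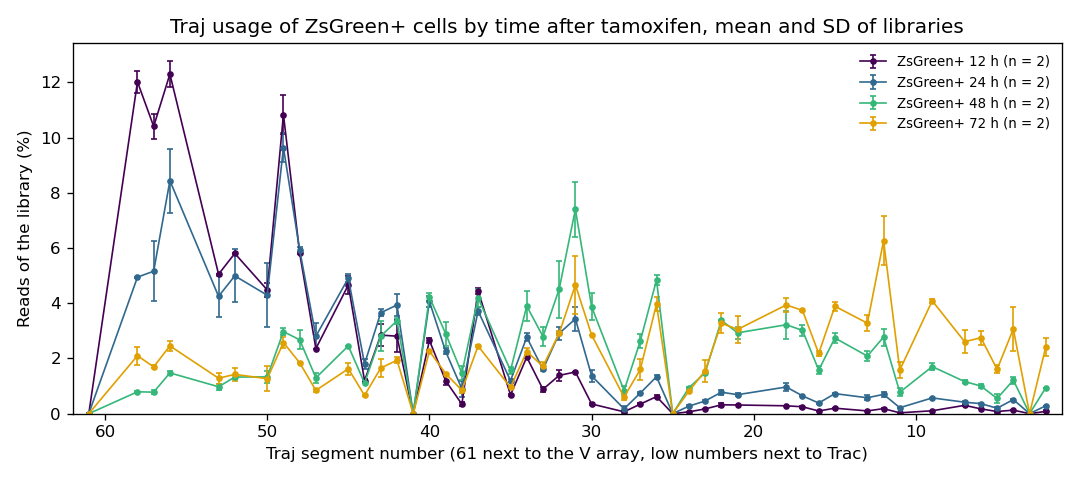
Use of each Traj segment in ZsGreen+ DP thymocytes at 12, 24, 48 and 72 h after tamoxifen (n = 2 libraries each). The x axis is the Traj number, from the V array to Trac, and the y axis is the share of the reads of a library in percent. Points are means and bars SD. Traj58 stands at 12.0% at 12 h and 0.792% at 48 h, while Traj12 moves from 0.182% at 12 h to 6.26% at 72 h.

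**Figure D3:**
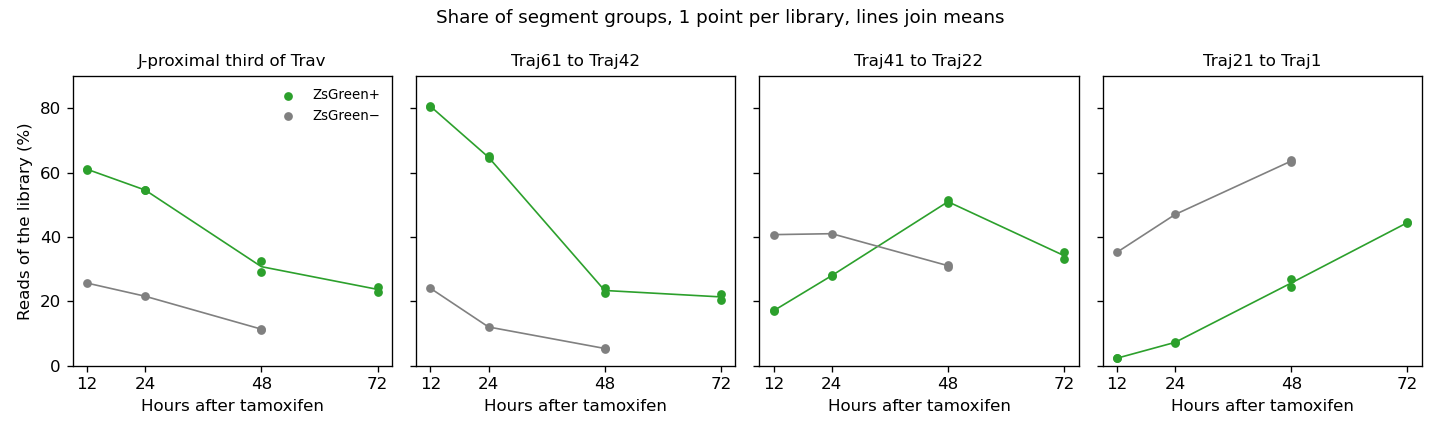
Shares of J-proximal Trav, Traj61 to Traj42, Traj41 to Traj22 and Traj21 to Traj1 against hours after tamoxifen, in percent of the reads of a library. Each point is 1 library, lines join means, green is ZsGreen+ and grey is ZsGreen−. In ZsGreen+ cells Traj61 to Traj42 moves from 80.6% at 12 h to 21.4% at 72 h and Traj21 to Traj1 from 2.33% to 44.5%.

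At 48 h, ZsGreen+ cells used more J-proximal Trav and more of the first Traj than ZsGreen− cells sorted at the same time (n = 2 each). Trav21-dv12 was 1.67% ± 0.430 in ZsGreen+ and 0.391% ± 0.0456 in ZsGreen− cells (log2 2.09, SE 0.22, adjusted p = 0.000566), and Trav1 was 1.38% ± 0.551 and 6.65% ± 0.160 (log2 −2.26, SE 0.50, adjusted p = 0.0109). Traj48 was 2.68% ± 0.346 and 0.523% ± 0.0328 (log2 2.35, SE 0.11, adjusted p = 1.41e-09), and Traj2 was 0.938% ± 0.00579 and 4.97% ± 0.167 (log2 −2.41, SE 0.16, adjusted p = 1.36e-08). Other V segments higher in ZsGreen+ cells were Trav3-4 (log2 2.47), Trav14-3 (2.22), Trav13-4-dv7 (1.89), Trav4-4-dv10 (1.89) and Trav8-2 (1.79). Lower were Trav2 (log2 −1.60), Trav12d-2 (−1.35), Trav13d-1 (−1.06), Trav3d-3 (−1.06) and Trav13d-2 (−0.92). Traj57, Traj56, Traj52, Traj49 and Traj58 had log2 changes of 2.35, 2.33, 2.32, 2.30 and 2.29, and Traj4, Traj5, Traj6, Traj11 and Traj9 changes of −2.38, −2.30, −2.16, −1.78 and −1.75.

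By list, 19 of 29 J-proximal Trav were higher at 48 h (23 when adjusted over the list alone). The number higher was 16 with TMM factors, 23 with DESeq2 and 14 with unique rearrangements. Of 28 central Trav, 1 was higher and 3 lower (1 and 1 when adjusted over the list alone), and 7 of 28 J-distal Trav were lower (6 when adjusted over the list alone). All 13 of Traj61 to Traj42 were higher and 13 of 14 of Traj21 to Traj1 lower, also when adjusted over each list alone. Traj41 to Traj22 had 11 of 16 higher, also when adjusted over the list alone, 8 higher and 3 lower with TMM factors, and 6 and 4 with DESeq2. All 3 of Traj61 to Traj56 were higher and all 6 of Traj9 to Traj2 lower, also when adjusted over each list alone. Trav17 to Trav23 had 4 higher of 6 and the Trav also named as Trdv 4 of 10, each 5 when adjusted over the list alone, and the former 2 with unique rearrangements. Trav1 and Trav2 were both lower, also when adjusted over the list alone, and 1 of 2 Trdv joined to Traj was higher (2 when adjusted over the list alone, with DESeq2 or with unique rearrangements). The mean Traj number was 30.8 ± 0.533 and 18.7 ± 0.102, the J-proximal share 30.8% ± 2.36 and 11.3% ± 0.260, the rank correlation 0.256 ± 0.0110 and 0.1004 ± 0.00742, and the effective number of pairs at 71154 reads 1720 ± 21.6 and 1341 ± 12.7. Exact two-sided permutation tests of 2 against 2 libraries cannot go below p = 0.333, the value each of them gave (adjusted p = 0.333). In edgeR, 31 of 88 V segments (21 higher, 10 lower) and 37 of 43 J segments (24 higher, 13 lower) were called, the J split was 19 and 18 with DESeq2, and the J median moved by −0.48 with TMM factors and −0.57 with DESeq2. The V count was 15 without ZsGreen+ replicate 2, 9 without ZsGreen− replicate 1 and 8 without ZsGreen− replicate 2.

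At 12 and 24 h each comparison rests on 1 shallow ZsGreen− library, which was assumed to vary like the other groups, so the tests have no replicate check on the ZsGreen− side. No other scaling was run at these times, so a common shift of shares was not separated. At 12 h, Trav21-dv12 was 14.7% ± 0.147 in ZsGreen+ cells and 2.14% in the ZsGreen− library (log2 2.78, SE 0.29, adjusted p = 0.000309), and Traj58 12.0% and 1.49% (log2 3.02, SE 0.17, adjusted p = 9.61e-10). Trav1 was 0.0326% and 2.06% (log2 −5.97, SE 0.64) and Traj11 0.0303% and 1.26% (log2 −5.36, SE 0.28). At 24 h, Trav21-dv12 was 5.95% ± 0.787 and 0.75% (log2 2.99, SE 0.30, adjusted p = 0.000605), Traj58 4.95% and 0.236% (log2 4.39, SE 0.20, adjusted p = 5.62e-10), Trav15d-2-dv6d-2, Trav3-1 and Trav2 had log2 differences of −3.26, −2.87 and −2.57, Trav5-1 had one of −2.24 (SE 0.28, adjusted p = 0.00169) and Traj4 was 0.511% and 4.15% (log2 −3.01). In edgeR, 40 of 88 V segments (11 higher, 29 lower) and 39 of 43 J segments (11 higher, 28 lower) were called at 12 h, and 31 V (14 and 17) and 37 J segments (15 and 22) at 24 h. By list, with the counts when adjusted over the list alone in parentheses, J-proximal Trav had 10 higher (9) of 29 at 12 h and 12 (12) at 24 h. Central Trav had 15 lower (16) and 7 lower (6) of 28, and J-distal Trav 14 lower (14) and 10 lower (10) of 28. Traj61 to Traj42 had 10 (10) and 13 (13) higher of 13, Traj41 to Traj22 had 1 higher and 14 lower (1 and 14) and 2 higher and 8 lower (2 and 8) of 16, and all 14 of Traj21 to Traj1 were lower at both times, also when adjusted over the list alone. Traj61 to Traj56 (3 of 3 higher), Traj9 to Traj2 (6 of 6 lower) and Trav1 with Trav2 (2 of 2 lower) had these counts at both times, also when adjusted over the list alone. Trav17 to Trav23 had 2 higher of 6 and Trav also named as Trdv 4 higher and 1 lower of 10 at both times, also when adjusted over the list alone. Of 2 Trdv joined to Traj, 1 was higher at 12 h (2 when adjusted over the list alone) and 2 at 24 h, also when adjusted over the list alone.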

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

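The tests of explanations in this part, the splits of the libraries among them, were chosen after the results were seen. In HYa DP thymus, Traj9 to Traj2 took 22.04% of the reads of replicate 2, against 14.6%, 14.2% and 13.8% in the others, a gap of 0.898 of the range (critical value 0.829). It was the 1 such gap among 21 values tested, and chance gives about 1 in 20 groups. The difference between ZsGreen+ and ZsGreen− cells at 48 h was also compared with that at 12 h. An edgeR test of the difference of both contrasts flagged 21 V segments and 38 J segments. All 21 V and 37 of the 38 J segments changed upward, for example Traj15 (log2 3.15, SE 0.17). The 12 h side rests on 1 shallow ZsGreen− library, which was assumed to vary like the other groups. These counts thus have no replicate check on that side. No other scaling was run, so a common shift of shares was not separated, and no conclusion is drawn from the counts.

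HYa replicate 2 also had the lowest share of the Trav17-Traj57 clonotype in HYa thymus (8.28%). WT cells or reads in this library are argued against, since diluting the clonotype would take 58.9% of WT and bring a Trdv share of 1.85%, and the observed share was 0.00123%. Mature T cells are argued against too, since they would have to make up 91.7% and bring the productive share to 84.4%, while it was 70.5%, below the 72.4% to 74.1% of the other HYa thymus libraries. Other technical causes stay open, and no biological explanation was tested.

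The first Traj were higher again at 72 h than at 48 h in ZsGreen+ cells. Low depth is argued against, since the deeper 72 h library (474226 reads) had 6.40% of its reads in Traj61 to Traj56, against at most 3.16% at 48 h. A candidate explanation is that cells labelled earlier in development reached the sorted stage later. The change of −16.8 percentage points in Traj41 to Traj22 decides nothing, because shares sum to a whole and Traj21 to Traj1 gained. No ZsGreen− library at 72 h was among those analysed, so this stays open.

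In HYa, Traj61 to Traj58 and several V segments on the Trac side of Trav17 were nearly missing. Too few reads are argued against, since the WT share would give 4466 reads of these Traj in the shallowest HYa library. Loss of Traj61 to Traj58 from the HYa alleles may account for the J part, whose highest share was 0.000177% in any HYa library. Loss of all 8 V segments nearer Trac than Trav17 is argued against, since their summed share was at least 0.348% in each HYa library, but 10668 of the 11127 such reads in HYa thymus were of Trav19 and 376 of Trav18, so loss of the others stays open. Whether these V segments were named correctly by the clone tables, or lie elsewhere on the HYa allele, was not tested.

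Splits of the same libraries were refitted. For HYa against WT, 2 of 35 splits called as many V segments as the real split (25, highest other 30) and 2 of 35 as many J segments (23, highest other 31), so chance is not excluded by this count. The other split places HYa replicate 2 with the WT libraries and the next highest called 8 V and 12 J segments, which points to a structure of the samples. For INT1-2-KO against WT, 1 of 10 splits reached the real counts of 15 V and 5 J segments, and the highest other called 0, but 10 splits are too few for a share under 0.05.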

How the results depend on the processing

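Settings without the Trav17-Traj57 clonotype or without libraries under 30000 reads were chosen after the data were seen. Of 159 counts of called segments, 128 stayed within 1.5 times of the count reported and 31 moved. Of 214 single values, 8 changed direction. Their side of the threshold says nothing on stability for INT1-2-KO, spleen and 48 h, where the exact test cannot pass it, and the 14 HYa values no longer past it all leave out 1 library, which the smallest possible p then explains. Of 408 values of named segments, 379 kept direction and side of the threshold, 25 were no longer past it and 4 changed direction. The cause was not tested where none is given. V counts were 13 (HYa), 7 (INT1-2-KO), 6 (spleen), 10 (trend) and 10 (48 h) with Trav families, which leave fewer units to test, and 7, 11, 25 and 14 for INT1-2-KO, spleen, trend and 48 h with reads naming 1 gene. J counts for HYa were 3 with unique rearrangements, 6 with TMM factors, 7 with DESeq2 and 6 without the clonotype. J counts for INT1-2-KO were 8 with DESeq2, 3 with productive rearrangements and 10 with the compared groups alone.

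The 12 changes of direction all came from unique rearrangements or from leaving out the clonotype. The HYa difference in mean Traj number was −1.74 with unique rearrangements and −0.977 without the clonotype, Trav17 had log2 −0.51 and −0.12, and Traj57 −7.94 and −5.92. For spleen against thymus, mean Traj number became 1.60 and 1.43 and the J-proximal share 2.91 and 2.77 in these settings, and without the clonotype the rank correlation became 0.0018 and the effective number of pairs −155. Trend counts without libraries under 30000 reads were 49 V and 31 J.

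With the replicate number as a block, V counts were 32 (INT1-2-KO) and 35 (spleen), and no other count moved by over 1.5 times. For HYa and INT1-2-KO with WT the correlations of deviations do not settle whether the numbers pair the samples. Same-number correlations were 0.0606, 0.467 and 0.474 for HYa with WT and −0.0570, 0.255 and 0.309 for INT1-2-KO with WT. The best correlation with another number was higher for replicate 1 (0.476 and 0.382). It was lower for replicate 2 (0.0643 and 0.218) and for replicate 3 (−0.0942 and −0.102), so pairing by number stays open. In groups of 2, which give 1 independent value per comparison and are too few to decide, same-number correlations were −0.239 for spleen with thymus and 0.0840 for ZsGreen+ with ZsGreen− at 48 h. Between ZsGreen+ times they were 0.739 (24 and 48 h), 0.865 (24 and 72 h) and 0.769 (48 and 72 h), but −0.140, 0.0292 and 0.0496 for 12 h with 24, 48 and 72 h. Replicate 2 was the shallower library at 24, 48 and 72 h, so a shared number and depth were not separated there. The blocked trend called 51 V (32 higher, 19 lower) and 32 J segments (21 and 11).

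Leaving out 1 library gave V counts of 18 to 32 (HYa), 9 to 16 (INT1-2-KO), 3 to 24 (spleen), 39 to 50 (trend) and 8 to 21 (48 h), and J counts of 15 to 38, 3 to 8, 16 to 27, 31 to 34 and 35 to 37. A lone library left in a group was assumed to vary like the others. For HYa, mean Traj differences were 2.95 to 5.78, J-proximal shares 17.4 to 24.4, rank correlations 0.320 to 0.368 and effective pairs −1448 to −1278. For INT1-2-KO they were 3.11 to 4.27, 10.7 to 14.7, 0.207 to 0.216 and −505 to −396, for spleen −3.32 to −0.493, −7.87 to −0.816, −0.0882 to −0.0397 and 177 to 348, and at 48 h 11.7 to 12.4, 17.8 to 21.1, 0.148 to 0.164 and 370 to 395. Trend r was −0.989 to −0.974, −0.989 to −0.967, 0.806 to 0.919 and 0.867 to 0.920. Depth limits the 12 h and 24 h ZsGreen− values most, where 3 counts are 0.0144% and 0.0139% of reads.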

Other observations

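The comparison of 72 h with 48 h and the counts of canonical CDR3 sequences were chosen after the data were seen. Between 48 and 72 h, ZsGreen+ cells gained both ends of the Traj array and lost its middle (n = 2 each). Traj58 rose from 0.792% ± 0.0387 to 2.10% ± 0.326 (log2 1.42, SE 0.12, adjusted p = 7.05e-07) and Traj5 had a log2 change of 1.53 (SE 0.21, adjusted p = 2.82e-05). Traj6, Traj2, Traj4 and Traj9 rose by 1.46, 1.37, 1.35 and 1.26 on the log2 scale. Traj39 fell from 2.90% to 1.45% (log2 −0.99, SE 0.14, adjusted p = 4.35e-05), and Traj40 and Traj34 had log2 changes of −0.90 and −0.79. All 3 of Traj61 to Traj56 and all 6 of Traj9 to Traj2 rose, 12 of 16 in Traj41 to Traj22 fell, Traj61 to Traj42 had 4 higher and 6 lower of 13, and 12 of 14 in Traj21 to Traj1 rose (13 when adjusted over the list alone). In all 34 of 43 J segments were called (16 higher, 18 lower), and edgeR called 0 V segments, with 10 at an unadjusted p under 0.05. No other scaling was run for this comparison. Adjusted over the list alone, 1 J-proximal Trav fell and 1 J-distal Trav, both of Trav1 and Trav2 and 1 Trdv rose.

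The pair Trav1-Traj33, known from MAIT cells, took 0.121% ± 0.0285 of WT reads and 0.00742% ± 0.00488 of HYa reads (exact two-sided permutation p = 0.0286, n = 3 and 4), and 0.0293% ± 0.00107 of INT1-2-KO reads (exact permutation p = 0.1, the smallest possible). In ZsGreen+ cells it stood at 0.000956%, 0.0215%, 0.0604% and 0.179% at 12, 24, 48 and 72 h. The 12 h value is at the floor, with 0.00191% in replicate 1 and 0 in replicate 2. Both lie under the share of 3 counts (0.00574% and 0.00443%). Trav1 as a whole was 4.15% of WT reads and 0.714% of HYa reads. It was also lower in INT1-2-KO than in WT and rose with time in ZsGreen+ cells, as given above. A change particular to the pair was not separated from that of Trav1. The pair of Trav11 or Trav11d with Traj18, known from invariant NKT cells, took 0.0531% ± 0.0199 of WT reads, 0.0341% ± 0.0155 of HYa reads (exact permutation p = 0.229) and 0.0337% ± 0.0165 of INT1-2-KO reads (exact permutation p = 0.2). With the canonical CDR3 only, the WT and HYa shares were 0.0146% and 0.00297% for the NKT pair and 0.0156% and 0.00134% for the MAIT pair (exact permutation p = 0.0286 for both). The INT1-2-KO shares were 0.00239% ± 0.00270 and 0.00487% ± 0.000616, below every WT library (exact permutation p = 0.1 for both, the smallest possible, n = 3 each). These shares rest on few reads. HYa thymus replicates 1 to 4 had 10, 19, 35 and 10 reads of the canonical NKT pair and 4, 19, 0 and 3 of the MAIT pair. INT1-2-KO replicates 1 to 3 had 45, 9 and 1 reads of the NKT pair, and the lowest WT library had 34. Productive reads made up 85.4% ± 0.126 in HYa spleen and 72.8% ± 1.68 in HYa thymus (exact permutation p = 0.0667, the smallest possible).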
